A study of Homo sapiens with 28 samples.

How the data were processed

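Poly(A)-selected RNA of HepG2 cells was sequenced in pairs of reads from directional libraries, per the labels. There were 7 groups (water, CdCl2, DMSO, TCDD, PFOS, BPA and TBTCl) with 4 libraries each, 28 in total, after 24 h without serum and 24 h of exposure. The labels describe 4 independent experiments with technical triplicates and do not state whether a replicate number marks the same experiment in every group. The values were deposited as integer read counts per gene, made by the authors with fastp, STAR and HTSeq on GRCh38, per the submitters' processing notes, which also name DESeq2. The versions, the annotation release and the strand setting of the counting are not given in the sources used here. The labels of the TCDD and PFOS libraries are those after an exchange that the series text records.

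The table held 63140 gene identifiers. The last entry was left out because the file ends without a line break there, so its values may be incomplete, and 63139 genes were kept. Symbols were at hand for 62541 identifiers, and 58126 were found in GENCODE release 29, from which gene types, transcript lengths and GRCh38 coordinates were taken. That release may differ from the one used for counting. Genes were kept for testing by filterByExpr of edgeR (minimum count 10), which left 18849 genes with 99.96% of the counts. Total counts ran from 28.9 M to 66 M (median 46.5 M), and 3 counts in a library correspond to 0.0435 to 0.104 CPM. Such floors, and intervals on counts, cover counting error only. Mean totals were 47.0 M in water, 51.1 M in CdCl2, 53.1 M in DMSO, 47.3 M in TCDD, 41.1 M in PFOS, 44.2 M in BPA and 36.1 M in TBTCl. TMM factors ran from 0.861 to 1.07. Libraries of a group differed from each other by more than counting error, with a chi-square per gene of 24.8 to 334, so that no library was a copy of another of its group. Libraries of different groups were not compared in this way.

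Differential expression was tested with edgeR 4.0.16 (quasi-likelihood, TMM scaling) in R 4.3.3. All 28 libraries entered a single fit with 7 group means and 21 residual degrees of freedom, and the common biological coefficient of variation was 22.0%. Each compound was compared with its vehicle, DMSO was compared with water, and the compounds were compared with each other, directly where they shared DMSO and as differences of changes for CdCl2. A gene was called at a Benjamini-Hochberg adjusted p under 0.05. Levels are CPM with TMM scaling, as mean ± SD of 4 libraries. The SE given with an edgeR log2 fold change is its size divided by the square root of the quasi-likelihood F statistic. DESeq2 1.42.0 (Wald test, default settings) served as the other tool. Because 4 against 4 libraries fall apart in 2.86% of genes by chance, that share is given beside the share of tested genes whose groups did not overlap.

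There were 23 gene lists with 358 entries, fixed from general knowledge before the data were examined, of which 308 entries were tested. They cover an imprinted gene network around PLAGL1, other imprinted genes, aryl hydrocarbon receptor targets, metallothioneins and zinc export, heat shock, NRF2, the unfolded protein and integrated stress response, cholesterol synthesis, fatty acid and triglyceride synthesis, PPAR alpha and fatty acid oxidation, LXR and RXR, CAR and PXR, bile acids, hepatocyte genes, estrogen-responsive genes, cell cycle, p53, inflammation, extracellular matrix, hypoxia, mitochondrial mRNAs, and markers of other cell types and of biliary cells. Lists were tested with camera of limma 3.58.1 (correlation 0.01), adjusted over 115 tests, then with an estimated correlation and with fry. The comparisons, the tests, the lists, the rule for named genes and most alternatives were set before the data were examined. Under the rule, the 6 genes with the largest rises and the 6 with the largest falls were named per comparison, among called genes with a symbol, at least 5 CPM in a group and no overlap between the groups. To these came the 2 genes with the smallest p of each list with at least 3 called members, up to 14 genes, and PLAGL1, H19, IGF2, CDKN1C and each called network member. Genes beyond the rule are examples from the lists or are stated to have been picked after their values were seen.

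Whether equal replicate numbers pair libraries was checked by correlating the deviations of libraries from their group means. The correlations of equal numbers ran from 0.123 to 0.540 for CdCl2 and water, 0.425 to 0.593 for PFOS and DMSO, 0.173 to 0.269 for BPA, 0.249 to 0.528 for TBTCl, 0.181 to 0.627 for DMSO and water, and -0.212 to 0.439 for TCDD. All but TCDD passed the minimum of 0.1 for every number, and 23 of 28 libraries correlated best with libraries of their own number. A fit with the replicate number as a block is therefore given as an alternative, and its values appear beside those of CdCl2, PFOS and TBTCl, where the numbers paired the libraries and it moved counts. For BPA, where the numbers also paired the libraries, and for TCDD, where they did not pair all, the block's values are given with the other alternatives.

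The procedure was tested on simulated data of 18364 genes of which 200 were changed. Of the genes changed 2-fold it recovered 48% in a comparison of the CdCl2 design, 65% for TCDD, 54% for PFOS, 58% for BPA and 53% for TBTCl, and of those changed 1.5-fold 15%, 27%, 26%, 15% and 19%. False calls made up 0%, 3.16%, 2.44%, 6.41% and 6.49% of the calls. Every simulated group had the means of DMSO and the same spread, so these rates differ by the genes drawn and the library sizes, not by compound. The simulated libraries were independent, without differences shared by replicate number and without an outlying library.

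Alternatives changed 1 choice at a time: scaling (DESeq2 size factors, upper quartile, library size alone), filtering (none, or at least 1 CPM in 4 libraries), DESeq2, a fit to the 8 libraries compared, the block, stricter thresholds, and leaving out each library in turn. A transcript length offset, PFOS against water, the block without TBTCl replicate 4 or water replicate 3, and list tests without these libraries were added after the data were seen. Calls were also counted for all 35 divisions of the 8 libraries of a comparison into 4 and 4, and for 70 divisions for differences that involve CdCl2. The covariance of fold changes between compounds was set against simulated unchanged groups, and this covariance and the sharing of calls were recomputed with controls split into 2 and 2. Some genes that the rule names are not reported here. Genes that mark sex were not analysed here.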

Results

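Messenger RNA was sequenced from HepG2 cells, an established human liver cancer line, after exposure to 1 of 5 environmental chemicals. The 28 libraries fell into 7 groups of 4, and per the labels' protocols they came from 4 independent experiments. The compounds were cadmium chloride (CdCl2) at 0.5 µM with water as its control, and TCDD at 100 nM, PFOS at 10 µM, BPA at 75 µM and TBTCl at 0.1 µM, all 4 with DMSO as their control. Cells were deprived of serum for 24 h and then exposed for 24 h. The title of the series concerns a network of imprinted genes, which are genes expressed mainly from the copy inherited from a single parent, in fatty liver disease. Total counts per library ran from 28.9 M to 66 M, with a median of 46.5 M. At these depths 3 counts corresponded to 0.0435 to 0.104 CPM, counts scaled to library size, and this floor covers counting error only. Of 63139 gene rows, 18849 were expressed highly enough to be tested, and they held 99.96% of all counts. Values below are mean CPM ± SD with n = 4 per group, and fold changes and adjusted p values are from edgeR.

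The series text records that the TCDD and PFOS labels were exchanged after deposit, so known target genes were examined first. CYP1A1, the cytochrome P450 enzyme that dioxins induce through the aryl hydrocarbon receptor, stood at 4613 ± 1486 CPM in the TCDD libraries and at 8.37 ± 6.54 CPM in DMSO. In the PFOS libraries it stood at 7.51 ± 7.18 CPM. The lowest TCDD library had 2841 CPM of CYP1A1, above every library of the other groups, of which the highest was BPA replicate 2 at 462 CPM. CYP1B1, another target of this receptor, was at 5.50 ± 1.04 CPM in TCDD and 0.0539 ± 0.0464 CPM in DMSO. The metal-binding protein gene MT2A, which cadmium is known to induce, was at 127 ± 57.3 CPM in CdCl2 and 38.6 ± 18.6 CPM in water (adjusted p = 0.687). MT1X was at 0.611 ± 0.166 CPM against 0.277 ± 0.225 CPM (adjusted p = 0.898), and the haem-degrading enzyme HMOX1 was at 87.6 ± 17.9 CPM against 85.1 ± 12.4 CPM (adjusted p = 0.970).

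**Figure D1:**
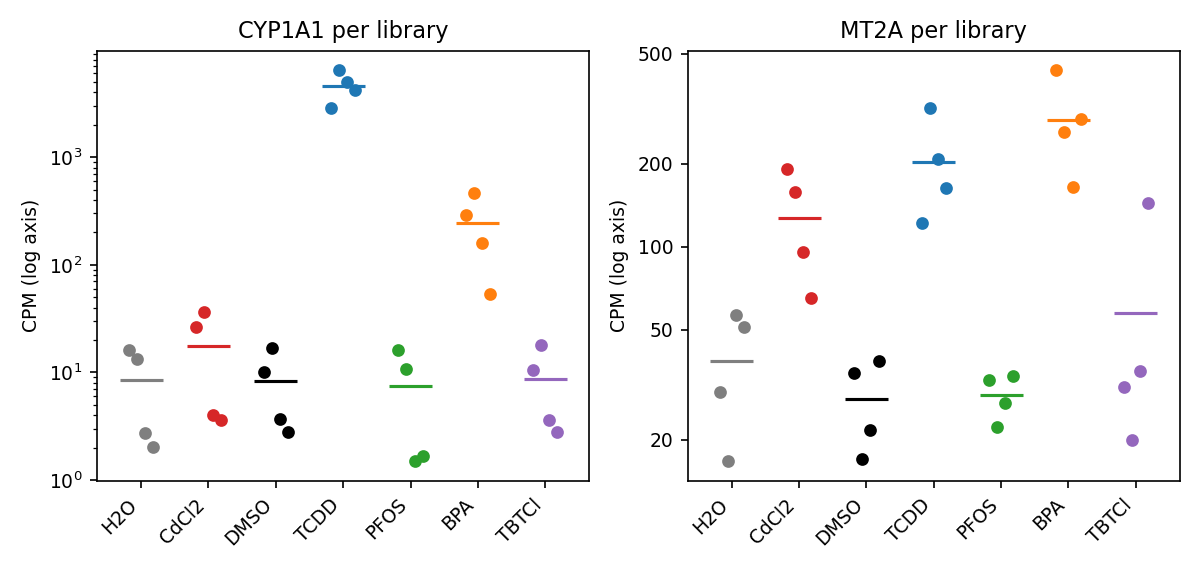
CYP1A1 (left) and MT2A (right) in each of the 28 libraries, in CPM on log axes, with a point per library and a bar at the group mean. The 4 TCDD libraries sit highest for CYP1A1 (mean 4613 CPM), followed by BPA (mean 242 CPM), while MT2A means are 127 CPM in CdCl2, 202 CPM in TCDD and 287 CPM in BPA.

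The BPA and TCDD libraries each stood apart from all other groups in a principal component analysis of the tested genes. The first component held 24.0% of the variance and placed the BPA libraries between -97.7 and -67.4. No other library lay below -6.06 on it. The second component held 17.0% and placed the TCDD libraries between 53.8 and 74.6. TBTCl replicate 4 had the next highest value on the second component, 21.3, and the highest of all libraries on the third, 101.

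**Figure D2:**
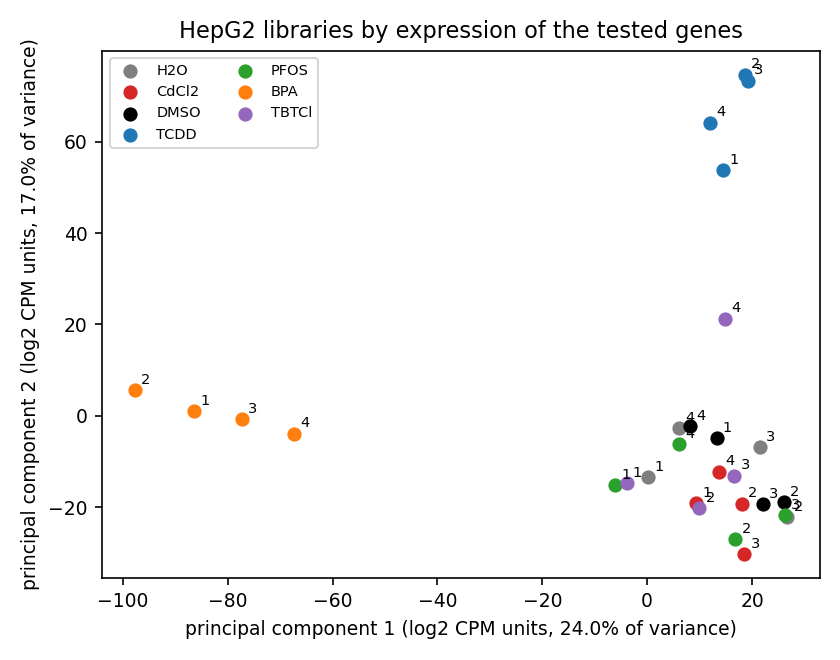
Principal components 1 and 2 of the log2 CPM of the tested genes, with a point per library, coloured by group and numbered by replicate. The BPA libraries lie below -67 on component 1, the TCDD libraries lie above 53 on component 2, and the other groups overlap.

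The comparison of CdCl2 with water asked which genes respond to a low dose of cadmium. Metallothioneins, small proteins that bind metal ions, rose most. MT1B stood at 16.9 ± 7.43 CPM in CdCl2 and at 0.196 ± 0.367 CPM in water (log2 fold change 6.37 ± 0.84 SE, adjusted p = 0.00160). MT1M rose from 0.445 ± 0.834 to 26.0 ± 13.0 CPM, 57.2-fold, MT1A rose 12.3-fold to 10.3 ± 5.52 CPM, and MT1F rose 7.18-fold to 14.7 ± 7.02 CPM. The water means rest largely on water replicate 3, which had 0.747 CPM of MT1B (others 0 to 0.0393) and 1.70 CPM of MT1M (others 0 to 0.0590). Without it the fitted log2 fold changes were 9.97 for MT1B, 9.71 for MT1M and 3.56 for MT1F, the first and second of these against few counts. All 4 lie in the metallothionein cluster of chromosome 16 (GRCh38), with MT1M starting at 56632233 and MT1F ending at 56660698. These were the 4 genes that passed the test, all 4 higher in every CdCl2 library than in every water library, and 0 genes fell (940 genes had an unadjusted p under 0.05). DESeq2 called 15 genes.

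Of the 9 measured members of the list of metallothioneins and zinc exporter, 3 rose, and 7 did so when adjusted over the list alone. The list stood higher as a set (camera, adjusted p = 4.07e-26, and adjusted p = 0.000476 with an estimated correlation). Metallothionein genes resemble each other closely, so reads may have been divided among them in counting and the values of single genes are uncertain. Among the other lists, the markers of leukocytes, endothelium and stroma were lower as a set (adjusted p = 0.0196 with an estimated correlation), although 0 of 9 members passed alone by edgeR, and 1 fell when adjusted over the list alone. Camera also called 7 lists whose calls ended with an estimated correlation. Cholesterol synthesis genes were lower as a set (median log2 fold change -0.25, adjusted p = 0.258 with an estimated correlation), as were fatty acid and triglyceride synthesis (adjusted p = 0.377 with an estimated correlation), cell cycle (0.794 by the same test), hypoxia and glycolysis (0.889) and the imprinted gene network (0.421). NRF2 antioxidant genes (adjusted p = 0.808 with an estimated correlation) and inflammation and acute phase genes (0.664) were higher as sets. None of these 7 lists had a member that passed in edgeR. Without water replicate 3 camera no longer called NRF2 (adjusted p = 0.122), inflammation (0.156) or hypoxia genes (0.0553).

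With the replicate number as a block, which these libraries' deviations supported, CdCl2 changed 28 genes, 17 up and 11 down, and 8 when water replicate 3 was left out. The 28 included MT1H (log2 fold change 6.26 ± 0.71 SE, adjusted p = 0.0135), the heat shock protein gene HSPA6 (3.66 ± 0.74, adjusted p = 0.0394) and the matrix-associated signalling protein gene CCN1 (1.20 ± 0.21, adjusted p = 0.0135). MT1H was at 1.88 ± 1.59 CPM in CdCl2, 0.0807 CPM in water replicate 3 and 0 CPM in the other water libraries. Its fold therefore rests on few counts. PHGDH, the first enzyme of serine synthesis, fell by 0.68 (SE 0.13, adjusted p = 0.0171). The block also brought the p53 targets past the threshold as a set (adjusted p = 0.0287 with the preset correlation; without the block, adjusted p = 0.877 with an estimated correlation) and took inflammation and acute phase genes out (adjusted p = 0.0605). These block genes were picked after their values were seen. In a fit to the 8 libraries of this comparison alone 0 genes passed, and without CdCl2 replicate 4 there were 10. In water replicate 3 MT1G stood at 26.4 CPM, against 0.511 to 3.40 CPM in the other water libraries and 142 ± 80.9 CPM in CdCl2.

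TCDD raised drug-metabolising genes that the aryl hydrocarbon receptor controls. CYP1A1 rose 552-fold (log2 fold change 9.11 ± 1.15 SE, adjusted p = 1.96e-06), CYP1A2 rose 194-fold to 12.8 ± 7.21 CPM and CYP1B1 rose 111-fold. MYADML2 (474-fold, to 12.2 ± 2.65 CPM), the phospholipase PLA2G4F (255-fold, to 53.6 ± 25.7 CPM), the lens membrane protein gene LIM2 (243-fold, to 117 ± 35.2 CPM) and the matrix proteoglycan FMOD (152-fold, to 22.1 ± 6.76 CPM) rose by more than 100-fold as well. The histidine-degrading enzyme HAL fell by 3.78 on the log2 scale, from 18.1 ± 13.2 to 1.30 ± 0.786 CPM (SE 0.90, adjusted p = 0.00569). DKK4, an inhibitor of WNT signalling, fell by 2.65, HOXD1 fell by 2.58, and ANGPTL8, a secreted regulator of triglyceride clearance, fell from 104 ± 42.9 to 18.1 ± 1.63 CPM. UGT2B4, which conjugates bile acids and steroids, fell by 2.30, and the related pseudogene UGT2B27P fell by 2.62. The UGT2B genes are near copies of each other, so reads may have been divided among them. Several of these folds rest on single libraries with few counts or high values. Without DMSO replicate 2 the log2 fold change was 9.72 for CYP1A1 TCDD vs DMSO and 8.51 for CYP1A2, and without DMSO replicate 3 it was 9.67 for MYADML2 (in place of 8.89) and -3.18 for HAL.

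In total TCDD changed 1743 genes, 1215 up and 528 down. Over all tested genes, the 4 TCDD and 4 DMSO libraries did not overlap in 15.3%, where chance gives 2.86%. Of 12 measured aryl hydrocarbon receptor targets 8 rose (10 adjusted over the list alone), among them the aldehyde dehydrogenase ALDH3A1, from 3.43 ± 1.90 to 362 ± 138 CPM, and AHRR, a repressor of the receptor, from 0.0460 ± 0.0378 to 1.96 ± 0.130 CPM. This list stood higher with an estimated correlation as well (adjusted p = 3.57e-05). It was the only list of TCDD for which that held, and 5 further lists were called by camera with its preset correlation.

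Among those lists, 4 of 9 metallothionein list members rose (5 adjusted over the list alone), including MT2A, from 28.1 ± 10.4 to 202 ± 83.7 CPM (list adjusted p = 0.500 with an estimated correlation). Of 15 NRF2 antioxidant genes 5 rose (6 adjusted over the list alone), with HMOX1 at 258 ± 47.8 CPM against 83.4 ± 9.89 CPM, and the glutathione synthesis subunit GCLM at 49.9 ± 9.89 CPM against 21.2 ± 1.48 CPM (list adjusted p = 0.421 with an estimated correlation). Of 20 cholesterol synthesis genes 7 fell (10 adjusted over the list alone). Among them the cholesterol carrier STARD4 fell by 0.74 on the log2 scale (list adjusted p = 0.284 with an estimated correlation).

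Of 17 fatty acid and triglyceride synthesis genes 6 fell and 2 rose (11 fell and 2 rose adjusted over the list alone; list adjusted p = 0.284 with an estimated correlation). The triglyceride-forming enzyme DGAT2 fell from 87.4 ± 9.28 to 49.2 ± 7.95 CPM, PNPLA3, a lipid droplet protein, fell from 47.3 ± 9.22 to 27.5 ± 1.58 CPM, and the lipogenic regulator SREBF1 fell from 148 ± 25.5 to 98.3 ± 19.2 CPM. The acyltransferase AGPAT2 rose from 9.27 ± 5.89 to 100 ± 49.0 CPM. Of 11 inflammation and acute phase genes 4 rose (4 adjusted over the list alone), including the iron-regulating hormone gene HAMP, from 1.34 ± 0.608 to 42.7 ± 7.55 CPM, and the NF-kappaB inhibitor NFKBIA (list adjusted p = 0.449 with an estimated correlation). CPT1A, the rate-limiting enzyme of mitochondrial fatty acid uptake, rose from 29.1 ± 1.25 to 130.2 ± 8.28 CPM (adjusted p = 9.78e-10). Its list, PPAR alpha and fatty acid oxidation, with 4 of 16 members up (5 up and 1 down adjusted over the list alone), was not called by camera. NR0B2, a repressor of bile acid synthesis, fell by 1.61 on the log2 scale. LUM, listed as a stromal marker, rose from 0.0116 ± 0.0146 to 1.01 ± 0.349 CPM, while PDGFRB of the same list fell.

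The comparison of PFOS with DMSO gave few calls. No protein-coding gene passed the test. The 3 genes that did, all lower in PFOS, were RPL4P5, a processed pseudogene of a ribosomal protein gene, which fell from 11.2 ± 2.20 to 5.23 ± 0.680 CPM (log2 fold change -1.10 ± 0.18 SE, adjusted p = 0.0238), and the antisense transcripts IDI2-AS1 (-1.65 ± 0.26, adjusted p = 0.0231) and ENSG00000258745 (-1.76 ± 0.32, adjusted p = 0.0468). The latter pair fell outside the rule for named genes and was picked after its values were seen. Reads of RPL4P5 cannot be told from those of its parent gene with certainty, and the strand setting of the counting is not given in the sources used here, so antisense transcripts are uncertain.

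CPT1A and the other 15 measured genes of PPAR alpha and fatty acid oxidation were higher as a set (median log2 fold change 0.11, camera adjusted p = 0.00672, and adjusted p = 0.421 with an estimated correlation), with 0 members called by edgeR and 1 up adjusted over the list alone. Cell cycle genes were also higher as a set (median 0.26, adjusted p = 0.859 with an estimated correlation), with 0 of 20 members called. In PFOS 1043 genes had an unadjusted p under 0.05, and DESeq2 called 127 genes, 126 of them down. With the replicate block, 84 genes fell and 0 rose. Of these 38 were annotated as antisense and 10 as protein-coding. The share of all reads in antisense genes was also lower, at 0.321 to 0.385% in the PFOS libraries, 0.386 to 0.423% in DMSO and 0.324 to 0.406% in water. The block called cholesterol synthesis genes lower as a set (adjusted p = 0.0291 with the preset correlation; without the block, adjusted p = 0.877 with an estimated correlation). Against water in place of DMSO 0 genes passed with or without the block, and leaving out single libraries gave 0 to 2 genes. A fit to the 8 libraries compared called 3 genes and shared 0 with the 3 named here.

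BPA changed more genes than any other compound, among them genes of glutathione synthesis, of the integrated stress response and of DNA replication. The glutathione synthesis enzyme GCLC rose from 72.0 ± 8.75 to 421 ± 181 CPM (log2 fold change 2.55 ± 0.22 SE, adjusted p = 6.19e-09), and DDIT3, a transcription factor of the integrated stress response, rose from 15.1 ± 2.36 to 69.4 ± 17.3 CPM. RRM2, which makes building blocks for DNA synthesis, fell from 150 ± 65.1 to 28.5 ± 8.08 CPM (-2.39 ± 0.33, adjusted p = 6.29e-06), and TOP2A, the topoisomerase of dividing cells, fell from 294 ± 102 to 65.8 ± 21.8 CPM. DKK1, a secreted WNT inhibitor, fell from 215 ± 27.5 to 8.80 ± 5.30 CPM, 24.4-fold.

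The genes with the largest rises in BPA were KLHDC7B (50.5-fold, to 46.9 ± 20.8 CPM), the lysosomal membrane protein gene LAMP3 (50.4-fold), the ATP-gated channel gene P2RX1 (41.9-fold), the complement receptor gene C5AR1 (38.2-fold, to 34.9 ± 5.70 CPM), the vitamin D-degrading enzyme gene CYP24A1 (31.9-fold, to 68.1 ± 43.8 CPM) and CYP1A1 (28.9-fold, to 242 ± 176 CPM). On the log2 scale LAMP3 rose by 5.66 and, without BPA replicate 2, by 4.98, and CYP1A1 rose by 4.86 and, without DMSO replicate 2, by 5.48. Besides DKK1, genes with large falls included KRTAP3-1 (-4.64 on the log2 scale), the somatostatin receptor gene SSTR3 (-4.48), the sodium channel gene SCN1A (-4.36, from 28.6 ± 7.96 to 1.41 ± 0.915 CPM) and LINC02413 (-4.06).

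BPA changed 6588 genes, 3268 up and 3320 down, of which 2763 changed by at least 2-fold, 822 up and 1941 down. Over all tested genes, the 4 BPA and 4 DMSO libraries did not overlap in 37.2%, where chance gives 2.86%. Of the genes that fell, 2001 were protein-coding and 603 antisense, and of those that rose, 2924 were protein-coding and 90 antisense. The share of all reads in antisense genes was lower in every BPA library (0.279 to 0.335%) than in every DMSO library (0.386 to 0.423%), and the water libraries, at 0.324 to 0.406%, overlapped with both. The split by direction depended on the scaling. With upper-quartile factors 2239 rose and 4345 fell, and with library size alone 2169 rose and 4321 fell, and the median of all genes moved by -0.13 and -0.12 on the log2 scale.

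Of 15 NRF2 antioxidant genes 13 rose under BPA (13 adjusted over the list alone), including GCLM, 4.59-fold, and the aldo-keto reductase AKR1B10, from 50.6 ± 27.8 to 415 ± 178 CPM, while HMOX1 stood at 91.3 ± 6.65 CPM against 83.4 ± 9.89 CPM (adjusted p = 0.531). Of 18 genes of the unfolded protein and integrated stress response 14 rose and 1 fell (14 and 1 adjusted over the list alone), with the phosphatase subunit PPP1R15A up 3.07-fold and XBP1, the transcription factor of the IRE1 branch, down by 0.40. The adjusted p with an estimated correlation was 0.0520 for each of these lists. Of 20 cell cycle genes 18 fell (20 adjusted over the list alone; list adjusted p = 0.570 with an estimated correlation).

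Some targets of receptors for foreign compounds also rose in BPA. Of 12 aryl hydrocarbon receptor targets 7 rose (7 adjusted over the list alone), including CYP2S1, 5.83-fold, and the amino acid transporter SLC7A5, 2.25-fold (list adjusted p = 0.149 with an estimated correlation). Of 10 CAR and PXR targets 6 rose (6 adjusted over the list alone), with CYP3A5 at 17.7 ± 5.93 CPM against 3.31 ± 1.27 CPM and the P450 electron donor POR up 2.13-fold (list adjusted p = 0.504 with an estimated correlation). Of 9 metallothionein list members 4 rose (5 adjusted over the list alone), with MT2A at 287 ± 112 CPM (list adjusted p = 0.574 with an estimated correlation).

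Lipid genes moved both ways under BPA. Of 20 cholesterol synthesis genes 9 fell and 2 rose (11 and 2 adjusted over the list alone; list adjusted p = 0.859 with an estimated correlation). In the list of PPAR alpha and fatty acid oxidation, 5 of 16 rose and 4 fell, with CPT1A up to 135.5 ± 13.4 CPM and the peroxisomal enzyme EHHADH down from 71.7 ± 12.2 to 32.3 ± 4.74 CPM. In the bile acid list 3 of 7 rose and 2 fell, with the bile acid exporter subunit SLC51B up 8.30-fold and CYP7A1, the rate-limiting enzyme of bile acid synthesis, down from 4.15 ± 2.99 to 0.307 ± 0.287 CPM (log2 fold change -3.84, and -4.51 without BPA replicate 3). Adjusted over the list alone the counts were the same for both, and neither list was called by camera.

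Of 17 hypoxia and glycolysis genes 7 fell under BPA (8 adjusted over the list alone; list adjusted p = 0.889 with an estimated correlation), and of 6 biliary and progenitor markers 3 fell (4 adjusted over the list alone), including the keratin KRT19, from 549 ± 44.0 to 266 ± 47.6 CPM (list adjusted p = 0.187 with an estimated correlation). Of 16 hepatocyte secreted and identity genes 5 fell and 2 rose (5 and 3 adjusted over the list alone). Alpha-fetoprotein (AFP) and the fibrinogen chains FGA, FGB and FGG fell, while the hepatocyte transcription factor HNF4A rose from 375 ± 35.7 to 522 ± 19.8 CPM. Of 14 p53 targets 6 fell and 1 rose (8 and 3 adjusted over the list alone). The gene that rose was the secreted stress factor GDF15, which went from 364 ± 28.1 to 2455 ± 564 CPM. Camera called 9 lists for BPA and 0 of them held with an estimated correlation.

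Among the few genes that TBTCl raised were some of lipid and bile acid handling, and of the lists they belong to, only LXR and RXR targets held with an estimated correlation. CPT1A rose from 29.1 ± 1.25 to 86.2 ± 10.6 CPM (log2 fold change 1.57 ± 0.17 SE, adjusted p = 2.29e-05), and SLC51B rose from 3.42 ± 1.53 to 22.6 ± 16.5 CPM (2.73 ± 0.45, adjusted p = 0.00603). SREBF1 rose from 148 ± 25.5 to 278 ± 45.4 CPM (0.91 ± 0.13, adjusted p = 0.00194), and LPCAT3, an enzyme of phospholipid remodelling, rose from 85.7 ± 6.97 to 151 ± 35.2 CPM. The cholesterol exporter ABCG1 rose from 0.157 ± 0.0942 to 0.924 ± 0.370 CPM. Rises were also found for the apolipoprotein genes APOC1 (2.73-fold) and APOA2 (2.03-fold), for TTC39C (1.93-fold) and for NR0B2 (1.90-fold). Without TBTCl replicate 4 none of these passed in the fit without the block, and all of them passed in the fit with the block.

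In total 27 genes passed for TBTCl, 20 up, all 20 of them protein-coding, and 7 down, with 0 protein-coding and 5 antisense. Of the 7 down, 6 were also called down in BPA against the same DMSO libraries. Whether TBTCl lowered them or their level was raised in the DMSO libraries was not tested. Over all tested genes, the TBTCl and DMSO libraries did not overlap in 4.87%, where chance gives 2.86% and the same share was 4.94% for PFOS and 2.45% for CdCl2. Of 11 LXR and RXR targets, genes of receptors for oxysterols and retinoids, 3 rose (4 adjusted over the list alone). This list stood higher with an estimated correlation as well (adjusted p = 0.0344). Camera called 6 further lists, all higher as sets. In the list of PPAR alpha and fatty acid oxidation 1 of 16 rose (4 adjusted over the list alone; list adjusted p = 0.149 with an estimated correlation), in fatty acid and triglyceride synthesis 1 of 17 (1 adjusted over the list alone; adjusted p = 0.473 with an estimated correlation), and in bile acid and FXR 2 of 7 (2 adjusted over the list alone; adjusted p = 0.377 with an estimated correlation). The others were CAR and PXR targets (adjusted p = 0.517 with an estimated correlation), inflammation and acute phase genes (0.610) and mitochondrially encoded mRNAs (0.877), with 0 members called by edgeR over all genes in each and 1, 3 and 0 adjusted over the list alone.

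TBTCl replicate 4 stood apart from the other 3 TBTCl libraries. Its expression fell with transcript length at -0.20 log2 CPM per doubling, while the other 27 libraries lay between -0.04 and 0.04. Without it 9 genes passed, 8 of them among the 27, and all 27 kept their sign. CPT1A, SREBF1, LPCAT3 and SLC51B (log2 fold change 2.12 in place of 2.73) still passed then. APOC1 (log2 fold change 0.83 in place of 1.45), APOA2 (0.59 in place of 1.02), TTC39C (1.00 in place of 0.95) and NR0B2 (0.78 in place of 0.92) did not. The LXR and RXR list had an adjusted p of 5.41e-05 with an estimated correlation, while inflammation and acute phase genes lost their call (adjusted p = 0.114). Camera then also called heat shock (higher, adjusted p = 0.0110), hypoxia and glycolysis (lower, 0.0233) and hepatocyte genes (higher, 0.0311), with adjusted p of 0.768, 0.847 and 0.684 with an estimated correlation, so that 9 lists were called in place of 7. With the replicate block 179 genes passed, 102 up and 77 down, and 84 did so when the block was fitted without TBTCl replicate 4. These 84 included APOC1 (edgeR adjusted p = 0.00241), TTC39C (0.00241), APOA2 (0.0439) and NR0B2 (0.0477). Falls among them included the antisense transcripts EML4-AS1 and IDI2-AS1, which with the block were also lower in PFOS against the same DMSO libraries. The block added HMOX1 (0.44 ± 0.09, adjusted p = 0.0223), and it called the unfolded protein and integrated stress response (adjusted p = 0.0184) and the hepatocyte genes (adjusted p = 0.0291) higher as sets with the preset correlation. Without the block, both had an adjusted p of 0.771 with an estimated correlation. In a fit to the 8 libraries alone 1 gene passed, with library size alone as scaling 8 rose and 1 fell (the median of all genes moved by -0.10), and without single DMSO libraries 5 to 7 genes passed. Other alternatives raised the count, to 55 without TBTCl replicate 1, 160 without TBTCl replicate 2 and 250 by DESeq2.

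**Figure D3:**
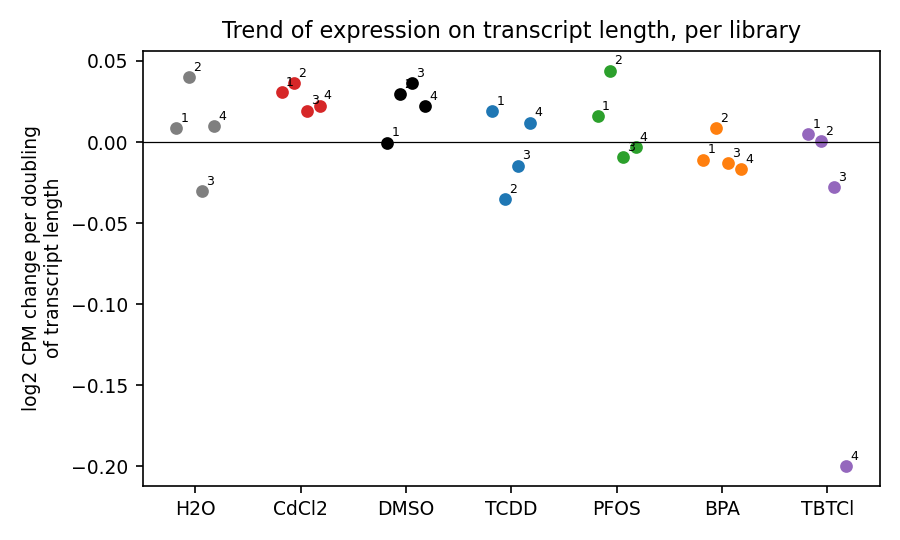
Slope of each library's log2 CPM on log2 transcript length, relative to the mean of all libraries, with a point per library numbered by replicate within its group. TBTCl replicate 4 lies at -0.20 and the other 27 libraries lie between -0.04 and 0.04.

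The vehicles were compared with each other because cadmium had another control than the other compounds. CYP1A1 stood at 8.37 ± 6.54 CPM in DMSO and 8.52 ± 7.19 CPM in water, and MT2A at 28.1 ± 10.4 and 38.6 ± 18.6 CPM. By edgeR 0 genes differed between DMSO and water, 431 had an unadjusted p under 0.05, and DESeq2 called 1.

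The imprinted gene network named in the series title was described with a list of 15 genes around the transcription factor PLAGL1, fixed from general knowledge. In the fit to all libraries, BPA was the only compound for which members passed over all genes, while for TCDD 1 member passed with no filter and 1 with the replicate block. GRB10, an adaptor that restrains insulin and growth factor signalling (chromosome 7, 50590063 to 50793462, GRCh38), rose from 21.1 ± 0.797 to 50.7 ± 12.7 CPM (log2 fold change 1.26 ± 0.14 SE, adjusted p = 1.64e-07). IGF2R, the receptor that clears IGF2, stood at 946 ± 47.7 CPM against 645 ± 115 CPM (0.55 ± 0.21, adjusted p = 0.0455). The sarcoglycan SGCE fell from 38.5 ± 1.31 to 28.1 ± 4.10 CPM, and GATM, an enzyme of creatine synthesis, fell from 3.82 ± 1.40 to 1.33 ± 0.612 CPM (adjusted p = 0.0309).

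Thus 2 of the 10 measured members rose and 2 fell under BPA, and 2 rose and 3 fell adjusted over the list alone. The 4 called members were not more frequent than among the other tested genes (Fisher's exact test, two-sided, p = 0.747), and the list's median of 0.11 was smaller than the shift of all genes with upper-quartile scaling. IGF2R lost its call in 11 of 17 alternatives (adjusted p up to 0.149), among them upper-quartile scaling and leaving out any single DMSO or BPA library except DMSO replicate 3. GATM lost its call without DMSO replicate 2, DMSO replicate 3, BPA replicate 1 or BPA replicate 2 (adjusted p up to 0.0927, in the last). GRB10 and SGCE kept theirs in all 17. With the block 5 members were called for BPA, 2 up and 3 down, and the same numbers were called by DESeq2.

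Under CdCl2, TCDD, PFOS and TBTCl 0 members passed in edgeR, and 0 did by DESeq2 or adjusted over the list alone. At an unadjusted p under 0.05 there were 2 for CdCl2 (MEST and GNAS), 2 for TCDD (DLK1 and GRB10), 0 for PFOS and 0 for TBTCl. PLAGL1 stood at 1.27 ± 0.390 CPM in CdCl2 against 1.70 ± 0.456 CPM in water, and at 1.96 ± 0.451 CPM in TCDD, 1.78 ± 0.394 in PFOS, 1.93 ± 0.254 in BPA and 1.54 ± 0.335 in TBTCl against 1.47 ± 0.268 CPM in DMSO. IGF2, a fetal growth factor, ranged from 2282 ± 1745 CPM in BPA to 4190 ± 2708 CPM in water. In every group replicate 4 was above replicate 1, and in BPA it was below DMSO of the same number in all 4 (1318 and 1973, 688 and 1916, 2469 and 4241, 4654 and 6216 CPM), with an adjusted p of 0.0589 with the block and of up to 0.788 over all alternatives. H19 and CDKN1C had total counts of 97 and 13 over the 28 libraries, and MEG3, NDN and DCN had 25, 12 and 5, too few to test at this depth.

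**Figure D4:**
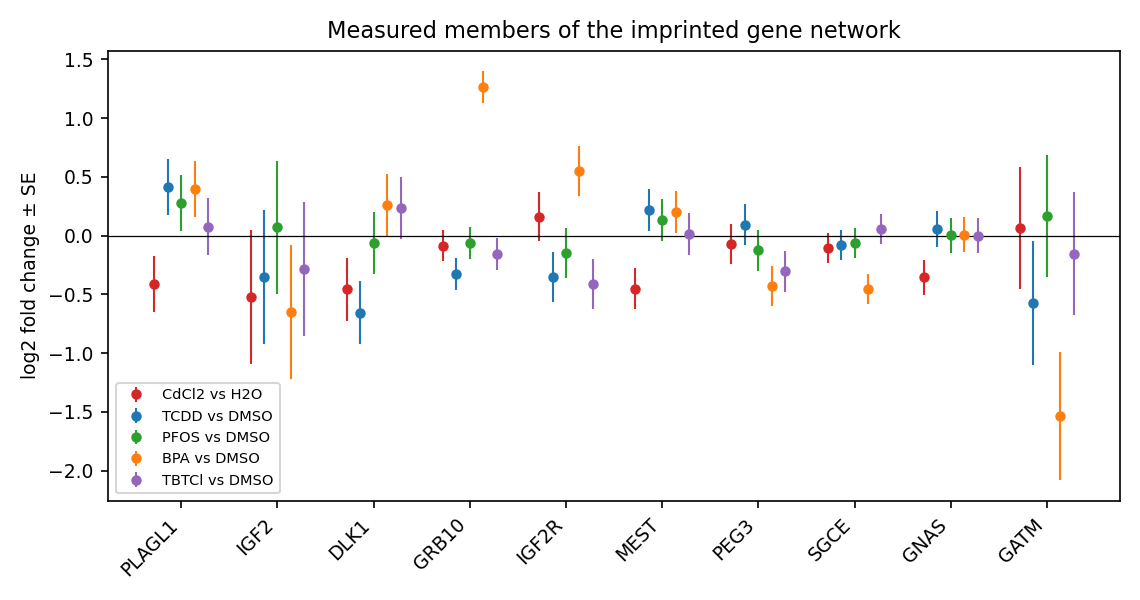
Log2 fold change ± SE of the 10 measured members of the imprinted gene network for each compound against its vehicle, from edgeR with n = 4 per group. GRB10 in BPA (1.26) and GATM in BPA (-1.54) lie farthest from 0.

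Imprinted genes outside this network moved in both directions. Of 26 measured, TCDD raised 4 and lowered 2 (4 and 5 adjusted over the list alone), and BPA raised 5 and lowered 5 (5 and 5 adjusted over the list alone). PEG10, a gene derived from a retrotransposon, fell from 3092 ± 778 CPM to 1141 ± 174 CPM in TCDD and to 634 ± 301 CPM in BPA. The long noncoding RNA KCNQ1OT1 rose from 30.6 ± 4.86 to 61.3 ± 4.94 CPM in TCDD and fell to 15.9 ± 4.64 CPM in BPA. PHLDA2, a placental growth repressor, rose from 4.35 ± 1.91 to 15.7 ± 4.68 CPM in BPA. The list was not called as a set for any compound (camera adjusted p from 0.341 to 0.765).

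The remaining lists were not called for any compound in the fit to all libraries without the block. Heat shock genes had 0 of 13 members changed by edgeR in each comparison (1 rose in CdCl2 and 1 in TBTCl adjusted over the list alone). Of 7 estrogen-responsive genes TCDD raised 1, IGFBP4, and BPA raised MYC and lowered PDZK1. Of 11 extracellular matrix and TGF beta genes TCDD lowered 1, CCN2, and BPA raised TGFB1 and TIMP1 and lowered TGFB2. The block called this list lower for TCDD (adjusted p = 0.0268 with the preset correlation; without the block, adjusted p = 0.258 with an estimated correlation).

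**Figure D5:**
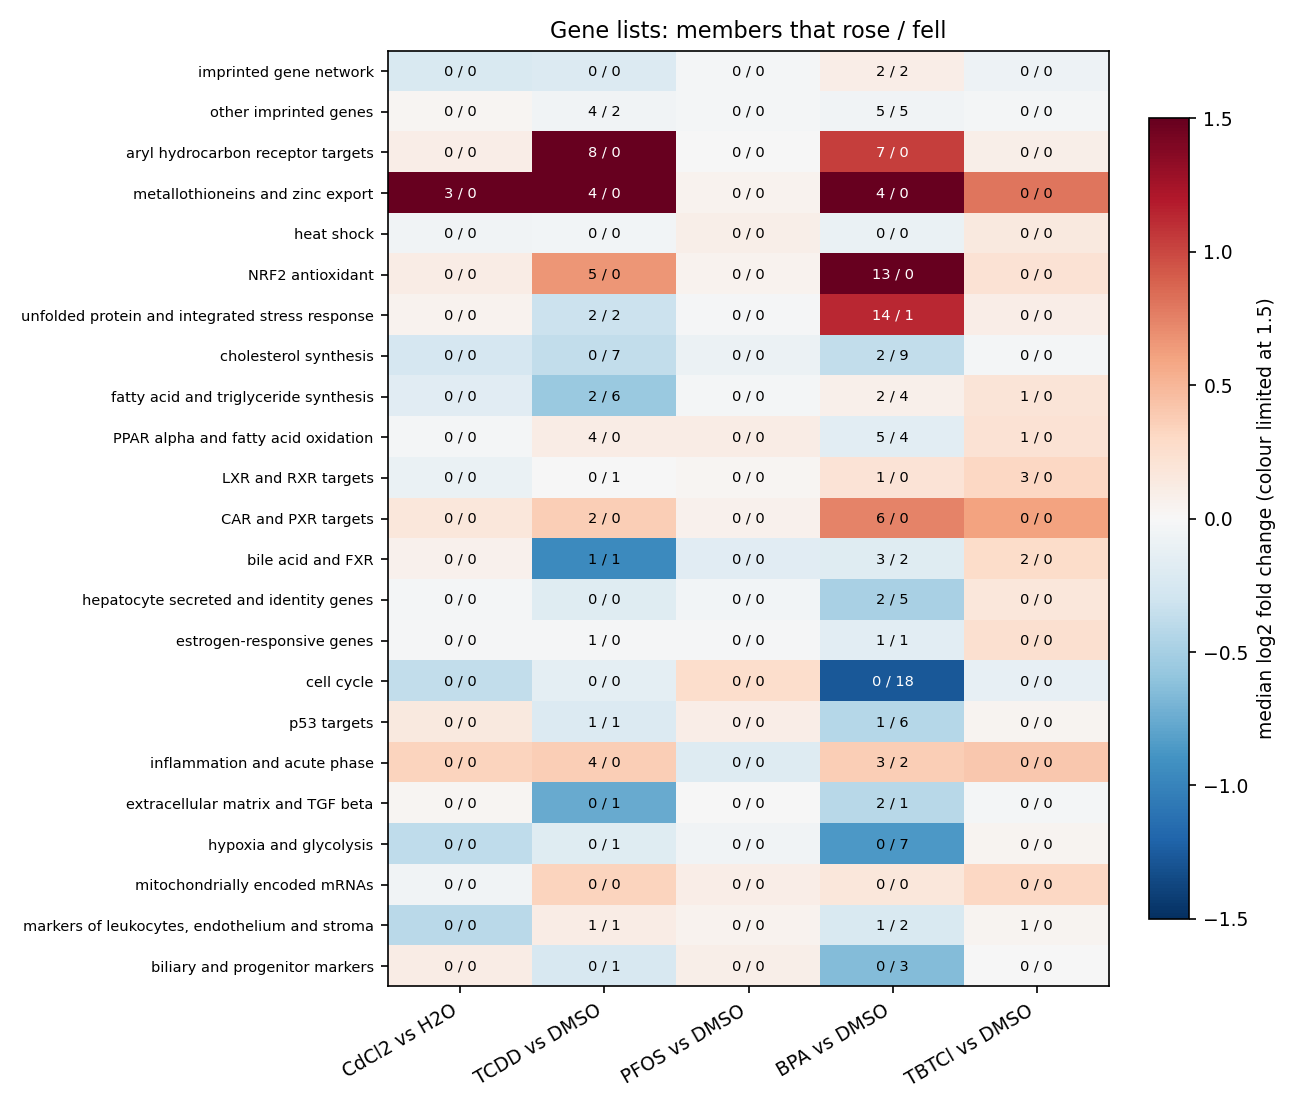
Median log2 fold change (colour) and numbers of members that rose / fell (edgeR, adjusted p under 0.05) for the 23 gene lists in the 5 comparisons with the vehicle. The highest counts are 18 cell cycle genes down, 14 stress response genes up and 13 NRF2 genes up, all in BPA.

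Direct tests of the differences between compounds, each at its single concentration, separated BPA and TCDD from the rest. GRB10 was higher in BPA than in TCDD, PFOS and TBTCl, by 1.59, 1.33 and 1.42 on the log2 scale (largest adjusted p = 8.32e-08), and its change was larger than that in CdCl2 by 1.35 (adjusted p = 4.09e-05). CYP1A1 was higher in TCDD than in BPA by 4.25 (SE 0.92, adjusted p = 0.000703), and MT2A differed between them by -0.51 (SE 0.47, adjusted p = 0.415). By edgeR, TCDD and BPA differed in 7218 genes, TCDD and PFOS in 2450, TCDD and TBTCl in 2420, PFOS and BPA in 5765, PFOS and TBTCl in 47, and BPA and TBTCl in 6564. The change in CdCl2 against its own vehicle differed from that of TCDD in 765 genes, of BPA in 3113, of TBTCl in 4 and of PFOS in 0 (1008 at an unadjusted p under 0.05; DESeq2 was not run on these differences).

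The genes changed by TCDD and by BPA were also compared, and both were measured against the same DMSO libraries. CPT1A, NQO1 and CYP1A1 were among 403 genes up in both, where independent lists would share 211, and DGAT2 and PEG10 were among 164 down in both, where 93.0 would be shared. A further 240 changed in opposite directions, such as KCNQ1OT1. The fold changes had a covariance of 0.0932, against 0.0261 for simulated unchanged groups with the same controls, a difference of 0.0671, and with the controls split into separate pairs the covariance had a mean of 0.0681 (0.0396 to 0.0905 over the splits). BPA and TBTCl shared 14 genes up (3.47 from independent lists) and 6 down (1.23). With split controls, which leave fewer libraries, they shared a mean of 1 up and 0 down. Their covariance difference was 0.0315, and with split controls the mean covariance was 0.0320 (0.00203 to 0.0504 over the splits). TCDD and TBTCl shared 3 up (1.29 from independent lists), and 7 changed in opposite directions (1.01), among them SREBF1 and NR0B2, which fell in TCDD and rose in TBTCl. The covariance difference of this pair was 0.00642 and the mean with split controls was 0.00935 (-0.0149 to 0.0296), a range that spans 0. For TCDD and PFOS the difference was -0.0207 and the mean with split controls -0.0179 (-0.0402 to 0.000692), with 0 shared calls by edgeR. The simulated libraries were independent and the controls were split by replicate number, although equal numbers paired the libraries of most groups. Both kinds of value may therefore be off, and small differences of either sign cannot be read as an effect.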

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

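The tests of RNA from other libraries and of sequencing depth for TBTCl replicate 4, and both tests on water replicate 3, were chosen only after the result was seen. In 6 of 119 sets of 4 replicate values, 1 library lay far from the other 3 by Dixon's ratio, where chance gives 5.95. CYP1A2 stood at 0.143 CPM in DMSO replicate 2 and at 0.0290 to 0.0371 CPM in the other 3, close to the floor of 3 counts. DKK4 was at 2.92 CPM in TCDD replicate 1 (others 1.19 to 1.30), and IGF2 was at 977 CPM in the same library (others 3118 to 3608). KRTAP3-1 was at 0.145 CPM in BPA replicate 4 (others 0.244 to 0.265). APOA2 was at 8485 CPM in TBTCl replicate 4 (others 3355 to 3806), and TTC39C was at 85.6 CPM in TBTCl replicate 2 (others 50.2 to 54.5).

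TBTCl replicate 4 lay at a distance of 0.797 from the other libraries of its group, where other libraries lay at 0.289 to 0.501 from theirs. Its expression fell with transcript length (slope -0.20), but removing that trend left the distance at 0.776 (others 0.288 to 0.495), and the trend held 5.06% of the variance, which argues against transcript length as the whole cause. Admixed RNA of a TCDD or BPA library is argued against by 2.78 CPM of CYP1A1. TBTCl replicate 4 had a total of 33.4 M and, after TMM scaling, the highest floor of 3 counts, 0.104 CPM. Low depth is argued against by TBTCl replicate 3 (total 32.8 M, floor 0.0960 CPM, distance 0.488) and PFOS replicate 3 (28.9 M, 0.102 CPM, 0.430). A difference in the cells or in the library preparation stays open, and no biological explanation was tested.

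With the replicate block, 84 genes were lower in PFOS than in DMSO, and 88.1% of them were noncoding or outside the annotation, against 28.8% of the tested genes. Over 52 pairs the genes on the opposite strand had a median log2 fold change of -0.0133 (SE 0.0284), against -1.42 for the genes themselves, but a lower rate of wrong-strand reads in PFOS libraries would leave those partners level, and the antisense share was below DMSO in every PFOS library (0.321 to 0.385% against 0.386 to 0.423%), so reads from the opposite strand stay open. The 84 genes were also lower than in water, with a median of -0.54 against -1.37 for DMSO, and DMSO was above water by a median of 0.79 and in 83 of the 84. A raised level in the DMSO libraries and an effect of PFOS cannot be told apart, since the genes were picked by their difference from DMSO. The same genes were lower in BPA (median -1.32), TBTCl (-0.93) and TCDD (-0.23), all against DMSO.

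Metallothionein genes were high in water replicate 3, with MT1G at 26.4 CPM (other water libraries 0.511 to 3.40) and MT1M at 1.70 CPM (0 to 0.0590). RNA from a CdCl2 library is argued against by the ratio of the MT1G rise to the MT1M rise, 14.9, where the CdCl2 libraries had 4.07 to 6.13. From counts alone this ratio was 15.6, with a 95% interval of 12.5 to 19.7. RNA from a TCDD library is argued against by MT1G itself. TCDD replicate 2, with the highest ratio of MT1G to CYP1A1, held 13.6 CPM of MT1G, less than water replicate 3. The test on CYP1A1 could not decide this. The 11669 CPM it set as needed lay above the 6410 CPM of that TCDD library, and water replicate 3 had 2.72 CPM. What raised these genes stays open, and no biological explanation was tested.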

How the results depend on the processing

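The transcript length offset, PFOS against water, and the block without TBTCl replicate 4 or water replicate 3 were chosen after the data were seen. Of 103 results on named genes, 71 were called, 57 of these kept their call in every alternative, 14 lost it in at least 1, and 0 changed direction while called. Over 1738 alternatives of these results, 66 lost a call and 3 gained one: MT2A in CdCl2 without a filter, MT1X in BPA in the fit to 8 libraries, and HMOX1 in TBTCl with the block. The counts of called genes for TCDD and BPA stayed within 1.5 times under scaling, filtering and DESeq2, while those of CdCl2, PFOS and TBTCl, which had few called genes, did not. Except where stated, the cause was not tested. Of the network's 15 members 5 had too few counts to test.

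With no filter the counts became 25 for CdCl2 (from 4), 78 for PFOS (from 3) and 111 for TBTCl (from 27), and 1 network member was called for TCDD (from 0). DESeq2 gave 15 for CdCl2, 127 for PFOS, 250 for TBTCl and 1 for DMSO against water (edgeR 0, with 431 at an unadjusted p under 0.05). Fits to the 8 libraries compared, with fewer residual degrees of freedom, gave 0 for CdCl2 (940 at an unadjusted p under 0.05 with all libraries) and 1 for TBTCl, and for PFOS 3 genes of which 0 were among the 3 called with all libraries. Upper-quartile scaling gave 23 for PFOS, and library size alone gave 9 for TBTCl. The transcript length offset gave 24 for PFOS.

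The block gave 28 for CdCl2, 2722 for TCDD (1688 up and 1034 down, from 1743), 84 for PFOS and 179 for TBTCl, and 1 network member for TCDD (lower). For BPA the block gave 8084 genes (4043 up and 4041 down, from 6588). It gave 8 for CdCl2 without water replicate 3 and 84 for TBTCl without TBTCl replicate 4. For TCDD the replicate numbers did not pair the libraries. It called 5 network members for BPA (from 4), and for TCDD it added the extracellular matrix list (lower, adjusted p = 0.0268) and mitochondrial mRNAs (higher, adjusted p = 0.0254), which without the block had adjusted p of 0.258 and 0.889 with an estimated correlation. Beyond these and the calls given for each compound, the block changed no call of a list or of a gene named by the rule. PFOS against water gave 0 genes by edgeR, and 0 with the block.

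By their construction stricter thresholds gave fewer genes. At an adjusted p under 0.01 there were 1023 for TCDD, 0 for PFOS, 3989 for BPA and 6 for TBTCl, and with at least a 2-fold change 880 for TCDD, 2763 for BPA and 14 for TBTCl.

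Leaving out single libraries gave 3 to 10 genes for CdCl2 (10 without CdCl2 replicate 4), 1221 to 1677 for TCDD, 0 to 2 for PFOS, 5253 to 6110 for BPA and 5 to 160 for TBTCl. For TBTCl the counts were 7, 6, 5 and 6 without DMSO replicates 1 to 4, and 55, 160, 35 and 9 without TBTCl replicates 1 to 4. The network members called for BPA were 2 to 4, with 2 without DMSO replicate 2, BPA replicate 1 or BPA replicate 2.

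With an estimated correlation 2 lists were called for CdCl2 (9 with the preset one), 1 for TCDD (6), 0 for PFOS (2), 0 for BPA (9) and 1 for TBTCl (7). With fry, which asks another question, there were 2 for CdCl2, 8 for TCDD, 0 for PFOS, 8 for BPA and 2 for TBTCl. With the controls split into 2 and 2, which leaves fewer libraries, the overlap of calls TCDD and BPA went from 567 to 206, and other overlaps from 3 to 1 for TCDD and TBTCl, from 3 to 0.167 for PFOS and BPA, from 1 to 0 for PFOS and TBTCl, and from 20 to 1 for BPA and TBTCl.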

Other observations

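The added lists and the divisions of the libraries for differences that involve CdCl2 were chosen only after the result was seen. Under BPA 15 of 20 cytosolic aminoacyl-tRNA synthetase genes rose and 1 fell, with a median log2 fold change of 0.60. The hypothesis that these genes rose as a set passed with an estimated correlation (camera of limma, adjusted p = 0.0339). That p was adjusted over the 20 tests of the 4 added lists and not over the 115 tests of the other lists. Since the list was chosen after the BPA result was seen, the p is not independent support. These genes load amino acids onto tRNAs, and the change may belong with the rise of the integrated stress response genes, which was not tested. Of 25 lysosomal genes 10 rose and 1 fell under BPA (median 0.19), and whether they rose as a set stays open (adjusted p = 0.295 with an estimated correlation). In TBTCl the 26 cytosolic ribosomal protein genes and 28 respiratory chain genes had medians of 0.43 and 0.42, with 0 members called by edgeR and adjusted p of 0.566 and 0.295 with an estimated correlation.

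IGF2 differed among replicates more than among compounds. In water it stood at 1532, 2917, 4482 and 7827 CPM in replicates 1 to 4, and in all 7 groups the value of replicate 4 was above that of replicate 1. CYP1A1 in water was at 16.1, 13.2, 2.72 and 2.04 CPM in the same libraries.

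The libraries of each comparison were divided in all 35 ways into 4 and 4, and the counts of called genes were set against those of the other divisions. The real division alone reached its count for TCDD (1743 genes, highest other division 0), BPA (6588, highest other 6) and TBTCl (27, highest other 0). That is 1 of 35, the smallest share these divisions can give. Other divisions mix treated and control libraries, so a real effect widens the spread within their groups and lowers their counts. Low counts there do not by themselves exclude chance. For CdCl2 (4 genes, highest other 8) and PFOS (3 genes) 2 of 35 were as high, so the number of calls cannot exclude chance. For CdCl2 the other division set water replicates 1, 3 and 4 with CdCl2 replicate 4 apart. The number does not consider which genes were called. The 4 of CdCl2 were metallothioneins. With all libraries the preset metallothionein list was higher with an estimated correlation, as given for CdCl2, which argues against chance for that list. Without water replicate 3 its adjusted p was 3.07e-05 (camera, estimated correlation). That library was chosen after its high metallothionein values were seen, so leaving it out favours the list and adds no support. For PFOS the division of replicates 1 and 4 from 2 and 3 gave 1185 genes, which points to a structure of the samples by replicate number. Among the 8 divisions that part all 4 equal numbers, the real one was the highest for CdCl2, PFOS, BPA and TBTCl, and the others gave 0. For DMSO against water all 35 gave 0 by edgeR (431 genes at an unadjusted p under 0.05, DESeq2 1).

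For members of the imprinted network in BPA, 4 were called and the highest other division had 0 (1 of 35 as high). This says nothing about the network itself, since no other division called more than 6 genes of all those tested. For CdCl2, TCDD and TBTCl (highest other 0) and for PFOS (highest other 1) the real count was 0. All 35 divisions match a count of 0 by construction, so nothing can be read from it. For the number of called gene lists chance cannot be excluded for any compound: 11 of 35 divisions gave as many as the 9 of CdCl2 (highest other 11), 19 as many as the 6 of TCDD (highest other 12), 32 as many as the 2 of PFOS (highest other 13), 15 as many as the 9 of BPA (highest other 16) and 3 as many as the 9 of TBTCl (highest other 10, adjusted over 23 lists). This number does not tell which lists were called, and many other divisions keep part of a compound's effect. It therefore decides nothing about single lists. The divisions that part equal numbers were not set apart for lists.

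The same limit holds for direct differences. The real division alone reached its count for TCDD and PFOS (2450 genes, highest other 0), TCDD and BPA (7218, highest other 133), TCDD and TBTCl (2420, highest other 2114), PFOS and BPA (5765, highest other 265) and BPA and TBTCl (6564, highest other 704), each with 1 of 35 as high. For PFOS and TBTCl other divisions reached it too (47 genes, highest other 489, 4 of 35 as high), although among the 8 divisions that part all 4 equal numbers the real one was the highest and the others gave 0. Among 70 divisions for differences that involve CdCl2, 2 were as high for TCDD (765 genes, highest other 840) and 2 for BPA (3113, highest other 3642). In both the higher value came from regrouping the control libraries. For TBTCl 5 were as high (4 genes, highest other 1916). For PFOS the real count was 0 by edgeR (1008 at an unadjusted p under 0.05, highest other 2763), so all 70 were as high by construction and nothing can be read from it.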
